A study of Homo sapiens with 2 samples.

How the data were processed

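Total RNA of 2 OECM1 cultures, 1 carrying the let-7i vector and 1 carrying the empty mCherry vector, was labelled with biotin as cRNA by the standard Affymetrix procedure, per the labels' protocols. The deposited values are 1-colour signal intensities, 1 per probe set and array, made with MAS5, per the submitters' processing notes. The MAS5 version and its settings are not given in the sources used here. The deposited intensities are on a linear scale, run from 0.130 to 48037, and have a mean of 500.1 on both arrays after 2% of the values are trimmed at each end, which is what scaling each array to a common mean gives. Such a scale removes any difference in total RNA per cell. MAS5 subtracts mismatch signal, which makes dim values noisy. The deposited table used here holds no detection calls, so a floor was set instead. The number of arrays limits the precision.

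Genes were named through the platform annotation, whose symbols were checked through Entrez IDs against a RefSeq table of assembly GRCh38.p14, and no symbol had to be changed. Of 54675 probe sets, 41097 carried 1 gene symbol and were used (41043 of their IDs were in the RefSeq table), 1801 carried several symbols and 11777 were not listed. The 54675 include 62 control probe sets. Probe sets with several symbols or none were left out, so some genes of the fixed lists are not reported here, 3 of the 20 panel genes among them. For 1 of the gene lists and its members no result is reported here, although it is counted among the lists. No coordinates are given because no genome build belongs to the deposited values. A gene was represented by its probe set with the highest mean log2 signal. The floor of each array was its 50th percentile over all probe sets, 88.0 for the empty vector and 79.5 for let-7i. A signal below the floor was set to the floor, which makes the ratio a lower bound, and a gene below it on both arrays got no ratio. For 178 of the 1144 genes below the floor on 1 array the bound leaves the direction open, because the floors of the arrays differ. Log2 ratios (let-7i vector over empty vector) were centred on their median over the genes measured on both arrays, a shift of 0.0036.

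With 1 array per group no test across samples was possible, and genes were called by size alone at 2-fold. Of 25 gene lists fixed before the data were examined, as were the floor, the threshold and all other settings tried except one named below, each one with at least 3 members above the floor was described by its median log2 ratio. The median was set against those of 10000 random lists of the same size, drawn with replacement within 20 bins of mean log2 signal, and was called apart below the 2.5th or above the 97.5th percentile. The let-7 target list was put together from background knowledge of reported and predicted targets. A test of seed matches in 3' UTRs was planned in case transcript sequences were at hand and was not run. The spread of 1 probe set was the SD of the difference in log2 ratio between the 2 brightest measured probe sets of a gene, divided by the square root of 2, and covers probe noise only.

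The named genes follow a fixed rule. They are the 10 highest and the 10 lowest log2 ratios among genes measured on both arrays whose measured probe sets all point one way, the 4 largest bounds each way, the up to 4 members of each list with the largest absolute ratio, and a panel of 20 genes. Sex-linked genes of the Y chromosome and XIST were never named. The 3'/5' signal ratio of the control probe sets was 0.948 for GAPDH and 1.21 for ACTB on the empty vector array, and 0.934 and 1.26 on the let-7i array.

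The alternatives were no centring, lowess centring (fraction 0.3, 3 iterations), quantile normalization, floors at the 25th and 65th percentile, the mean over a gene's probe sets at or above the floor on at least 1 array (centred anew on the median of these means), leaving out probe sets that can match several transcripts (IDs ending in _s_at or _x_at), and thresholds of 1.5-fold and 3-fold. Counting only genes measured on both arrays was added after seeing the data. The procedure was tested on simulated data built from the real signals and the probe noise, with 200 of 11974 genes changed. The changed genes were drawn from those measured on both arrays. Their mean signal was above the 25th percentile of the genes above the floor on at least 1 array. Recovery among dimmer genes and bounds was therefore not tested. All 50 genes changed 3-fold passed 2-fold in the right direction, as did 50 of 50 at 4-fold and 50 of 50 at 6-fold, and 3 of 50 changed 1.5-fold passed, as did 4 of 11774 unchanged genes. Probe sets below the floor were given the noise of the dimmest measured ones, so false calls among dim genes may be undercounted. The simulation holds no variation between cultures. Of 100 random lists without a shift, 2 were called lower. The work used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and Matplotlib 3.10.9.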

Results

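Gene expression was measured in OECM1, an established head and neck cancer cell line, after stable transfection with a vector that expresses the microRNA let-7i together with the red fluorescent protein mCherry. The same cell line carrying the empty mCherry vector was the control. let-7i belongs to the let-7 family, whose members repress messenger RNAs that carry matching sites, and the comparison asks which transcripts differ once let-7i is expressed. Each group had 1 array, so no difference had a replicate check, no p-value was computed and no SD between cultures could be given. The 2 arrays held 54675 probe sets each, with a median MAS5 signal of 88.0 on the empty vector array and 79.5 on the let-7i array. Of 19775 genes named by a probe set of their own, 11140 had a signal at or above the floor (the median signal of the array) on both arrays, 1144 on 1 array only and 7491 on neither. None of the 27 control probe sets for Bacillus subtilis genes, which these cells lack, reached the floor, the brightest having a signal of 65.1 on the empty vector array and 47.7 on the let-7i array. Log2 signals correlated at a Pearson r of 0.981 across the genes measured on both arrays, where genes are not independent replicates. The spread of 1 probe set, taken from 5807 genes with 2 measured probe sets, was an SD of 0.25 on the log2 scale. It was 0.34 for the dimmest 1452 of these genes and 0.15 for the brightest 1452.

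MMP1, an interstitial collagenase, had a signal of 153 with the empty vector and 3610 with let-7i, a 23.6-fold higher level. COL6A1, a chain of type VI collagen, was 7.67-fold higher, and its 2 measured probe sets gave log2 ratios of 2.55 and 2.94. Without probe sets shared between transcripts its log2 ratio was a lower bound of 1.11. The probe set then used (63.8 and 188.8) was below the floor with the empty vector. At the other end, TIMP3, an inhibitor of metalloproteinases, was 5.11-fold lower with let-7i, and its 4 measured probe sets gave log2 ratios between -3.01 and -2.35. IGFBP3, a binding protein of insulin-like growth factors, was 4.51-fold lower in its brightest probe set, and its 2 measured probe sets gave log2 ratios of -2.17 and -2.13.

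In all, 130 genes were at least 2-fold higher and 169 at least 2-fold lower with let-7i, together 2.43% of the 12284 genes above the floor on at least 1 array. Which direction held more genes depended on the scaling, with 154 higher and 145 lower after lowess centring and 158 and 142 after quantile normalization. Among the 10 highest ratios of genes measured on both arrays, with all measured probe sets pointing one way, were also CYB5A, a cytochrome b5 (10.8-fold), ADGRE1, an adhesion G protein-coupled receptor (6.93-fold), BNC1, a zinc finger protein of keratinocytes (6.09-fold), and CCBE1 (5.65-fold). The remaining genes of this set were IL32, a cytokine (4.72-fold), C1S, a complement protease (4.51-fold), DZIP1 (4.19-fold) and the chemokine CXCL2 (4.18-fold). The other measured probe set had a log2 ratio of 1.32 for BNC1 and of 0.33 for CCBE1. Among the 10 lowest ratios were TINCR, a gene of epidermal differentiation (4.04-fold), INHBB, an inhibin and activin subunit (4.03-fold), DDX60 (3.70-fold) and IFI27 (3.67-fold), both interferon-induced, and CLIC3 (3.61-fold). MNX1, a homeobox transcription factor, was 3.47-fold lower, AIF1L 3.33-fold and CLEC7A, a beta-glucan receptor, 3.28-fold. For genes below the floor on 1 array the fold is a lower bound. PTX3, a secreted pattern recognition molecule, was at least 8.48-fold higher with let-7i, DTNBP1 at least 4.38-fold, ZEB1 at least 4.24-fold and SH2D5 at least 3.89-fold. GABRP, a GABA receptor subunit, was at least 9.57-fold lower, ALPP, placental alkaline phosphatase, at least 9.52-fold, ZNF580 at least 5.95-fold and HCLS1 at least 5.45-fold. With a floor at the 65th percentile of each array, the log2 ratios of DZIP1 (0.94), CXCL2 (0.97), DTNBP1 (0.74) and SH2D5 (0.57) were under the 2-fold threshold, and without probe sets shared between transcripts so was that of CLEC7A (-0.78). That floor cut the folds of MMP1 (to a log2 ratio of 3.97), CYB5A (2.51), ADGRE1 (1.53), BNC1 (1.49), CCBE1 (1.145), TINCR (-1.40), AIF1L (-1.13), CLEC7A (-1.05), PTX3 (1.70), GABRP (-1.84), ALPP (-1.83), ZNF580 (-1.154) and HCLS1 (-1.03) by over 1.5 times, since it lies above their dimmer signal. Of 90 genes past 2-fold that had a second measured probe set, the second pointed the same way in 78 (86.7%), against 64.2% for all 5807 pairs. With that higher floor 62 genes were at least 2-fold higher and 71 lower, while a floor at the 25th percentile gave 654 and 1113.

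**Figure D1:**
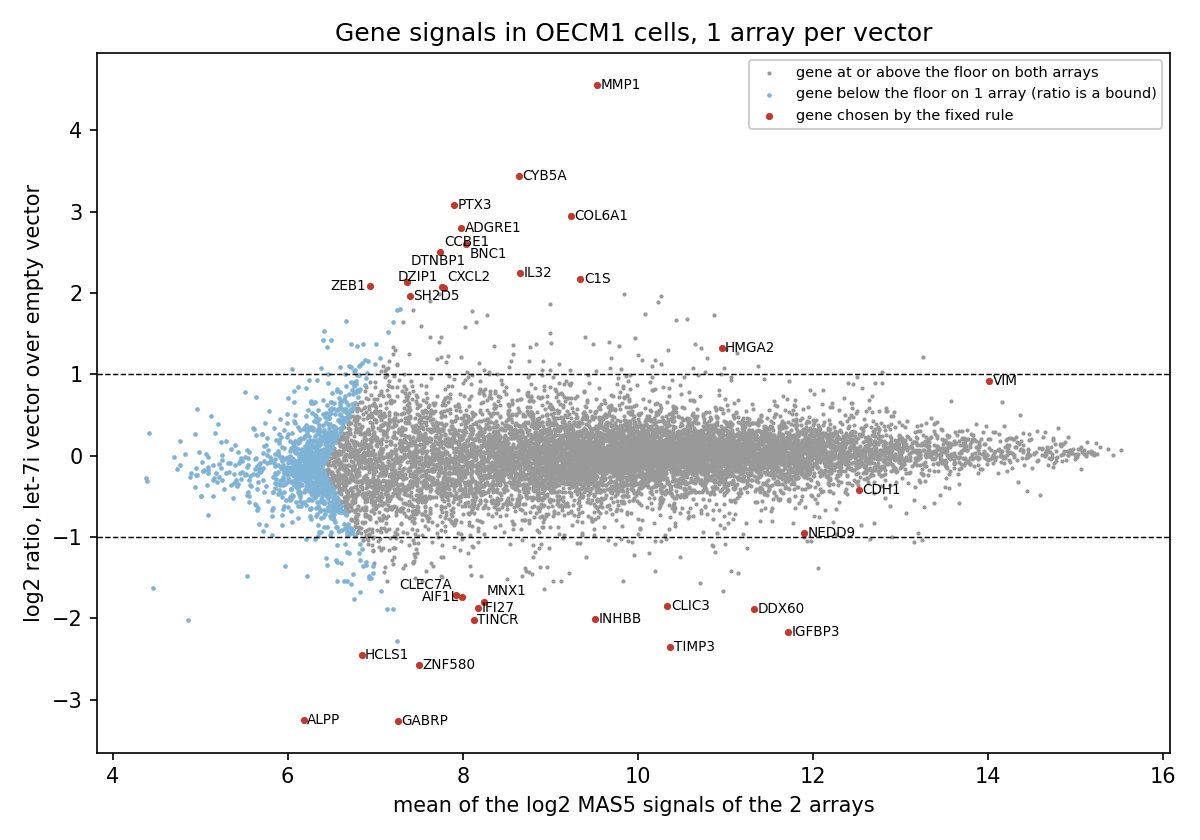
Log2 ratio of the MAS5 signals (let-7i vector over empty vector, 1 array each) against the mean log2 signal of the 2 arrays, for the 12284 genes above the floor on at least 1 array. Dashed lines mark 2-fold, blue points are lower bounds for genes below the floor on 1 array, and red points are genes chosen by the fixed rule, from MMP1 at 4.56 down to GABRP at -3.26.

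The mature let-7i is not measured by this kind of array, and no probe set was named for its gene or host transcript, so its level did not check the labels. Genes known or predicted to be let-7 targets were not lower as a group. Of 72 list members above the floor, 45 were higher and 26 lower with let-7i, 1 (CPEB1, named after its values were seen) had a bound that leaves its direction open, 1 gene was past 2-fold in each direction, and the median log2 ratio was 0.06. HMGA2, a chromatin protein and a well-known let-7 target, was 2.51-fold higher with let-7i (1251 and 3148), with log2 ratios of 1.12 and 1.33 in its 2 measured probe sets. The mean over its probe sets that reach the floor on at least 1 array, which takes in bounds of dim ones, was 0.75 after centring anew. BACH1, a transcription factor that binds heme, was 1.84-fold higher. EDN1, the precursor of endothelin, was 2.11-fold lower, but its 3 probe sets ranged from -1.17 to 0.30, and averaging probe sets for every gene and centring anew gave -0.63, and DNA2, a helicase and nuclease, was 1.70-fold lower.

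DICER1, which cuts microRNA precursors, had log2 ratios from -0.48 to -0.17 in 3 probe sets, and its brightest was 1.39-fold lower. LIN28B, an inhibitor of let-7 maturation, had signals of 143 and 110, a 1.30-fold lower level close to the floor. The insulin-like growth factor 2 mRNA-binding proteins differed little in their brightest probe sets, with log2 ratios of -0.06 for IGF2BP1, 0.37 for IGF2BP2 and -0.10 for IGF2BP3. The probe sets of IGF2BP1 ranged from -0.055 to 0.285, those of IGF2BP2 from -0.52 to 0.37 and those of IGF2BP3 from -0.88 to -0.03, the lowest being a dim one (148 and 80.9). CDK6, a G1 cell cycle kinase, had a log2 ratio of 0.08, with 6 probe sets between -0.15 and 0.16. CDC25A, a cell cycle phosphatase, had a log2 ratio of -0.16, but its 3 probe sets ranged from -0.17 to 0.56, and averaging probe sets and centring anew gave 0.10. MYC, a growth-promoting transcription factor, had a log2 ratio of 0.40. ARID3B was below the floor on the empty vector array and gave no more than a bound of 1.02-fold (a log2 bound of 1.56 with a floor at the 25th percentile). The median of the list lay within the middle 95% of the medians of 10000 random gene lists matched on signal, which ran from -0.061 to 0.075. With a floor at the 25th percentile it was 0.093, above the matching random range. In simulated lists of this size, a shift of -0.1 given to every member was found in 82 of 100 and a shift of -0.2 in 100 of 100. A decrease in only some of the members was not simulated, and the median may miss it.

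NEDD9, a scaffold protein that acts upstream of the small GTPase RAC1, was 1.93-fold lower with let-7i. Its signals were 5275 and 2747, and its 4 measured probe sets gave log2 ratios between -1.20 and -0.85. Each is more than 3 times the SD of 1 probe set over all signals (0.25), which covers probe noise only and no variation between cultures. For the dimmest of them (182 and 92.0, log2 ratio of -0.99) the SD at such signals was 0.34, and that multiple does not hold there. DOCK1, an exchange factor for RAC1, was 1.68-fold lower, with log2 ratios of -0.75 and -0.68 in 2 probe sets, and the related DOCK4 was 2.07-fold higher in its 1 measured probe set. DOCK3 was below the floor on both arrays, with signals of 8.06 and 35.0, and no fold is given. RAC1 itself had signals of 11200 and 12470, a log2 ratio of 0.15, and the focal adhesion adaptor PXN was 1.28-fold lower. Of the 23 members of the CAS, DOCK and RAC1 list above the floor, 15 were higher and 8 lower, and the median of 0.10 lay within the random range of -0.10 to 0.14. It lay just above the matching random range after quantile normalization (0.131) and with a floor at the 25th percentile (0.145), and was 0.059 with the mean of the probe sets.

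Epithelial genes were lower with let-7i. Of 28 members above the floor, 25 were lower and 3 higher, 5 were at least 2-fold lower and none at least 2-fold higher. OCLN, a tight junction protein, was 2.72-fold lower in its brightest probe set and lower in all 3. The membrane protease ST14 was 2.68-fold lower, and the epithelial transcription factors ELF3 and OVOL1 were 2.67-fold and 2.16-fold lower, the call of OVOL1 being lost with a floor at the 65th percentile (-0.925). CDH1, the adherens junction protein E-cadherin, was 1.34-fold lower (6785 and 5090), with log2 ratios of -0.55 and -0.42 in its 2 probe sets. The median log2 ratio of the list was -0.52, a 1.44-fold lower level, and 0 of 10000 random lists had a median as low.

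Mesenchymal genes were mostly higher. Of 25 members above the floor, 17 were higher and 8 lower, with 7 at least 2-fold higher and 1 at least 2-fold lower. The member lower by that much was FN1, fibronectin (log2 ratio of -1.04), named after its values were seen. ZEB2 and ZEB1, repressors of epithelial genes, were 3.74-fold higher and at least 4.24-fold higher. POSTN, a matrix protein, was at least 3.45-fold higher and MMP2, a gelatinase, at least 2.68-fold higher. VIM, the intermediate filament protein vimentin, was 1.89-fold higher (11960 and 22710) and TWIST1, a transcription factor, 1.11-fold higher. CDH2, N-cadherin, was below the floor on both arrays. The median log2 ratio was 0.52, a 1.43-fold higher level, and 0 of 10000 random lists had a median as high. The median was smaller, though still above the random range, over the members measured on both arrays (0.227), with a floor at the 65th percentile (0.249), without probe sets shared between transcripts (0.286) and with the mean of the probe sets (0.336). The 2-fold calls of ZEB1, ZEB2, POSTN and MMP2 rest on dim signals and were lost with a floor at the 65th percentile.

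Among squamous keratinocyte genes, 8 of 11 members above the floor were lower. KRT15, a basal keratin, was 2.72-fold lower and LY6D 2.85-fold lower, CNFN was 1.69-fold lower and the mucosal keratin KRT13 1.43-fold lower. The median was -0.30, against a random range of -0.28 to 0.20, and it lay within the matching random range in 4 of the alternative settings, the smallest shift being -0.15. The 2-fold call of LY6D was lost with a floor at the 65th percentile (-0.485). In the matrix and protease list, which holds MMP1, COL6A1 and TIMP3, 15 of 25 members were higher, and MMP7, matrilysin, was 1.74-fold lower. Its median of 0.16 was above the random range of -0.09 to 0.13, but was 0.03 and within its random range with a floor at the 25th percentile. Markers of other cell types were set beside these lists. Of 14 fibroblast markers 5 were above the floor, 4 of them higher, with a median of 0.77 (0.203, within its random range, with a floor at the 25th percentile), and 8 of the 14 also stand in another list. DCN, a matrix proteoglycan, was 1.97-fold higher (log2 ratio of 0.48 with a floor at the 65th percentile), FAP, a surface protease, 1.70-fold higher, and FBLN1, a matrix glycoprotein, 1.60-fold lower in its brightest probe set, with 4 between -0.68 and -0.18. Of the 16 leukocyte markers named here 6 were above the floor, with CD3E, a T cell receptor subunit, 1.92-fold lower at dim signals (173 and 90.4), and the median was 0.07, within the random range, and 2 of 12 endothelial markers were above the floor.

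**Figure D2:**
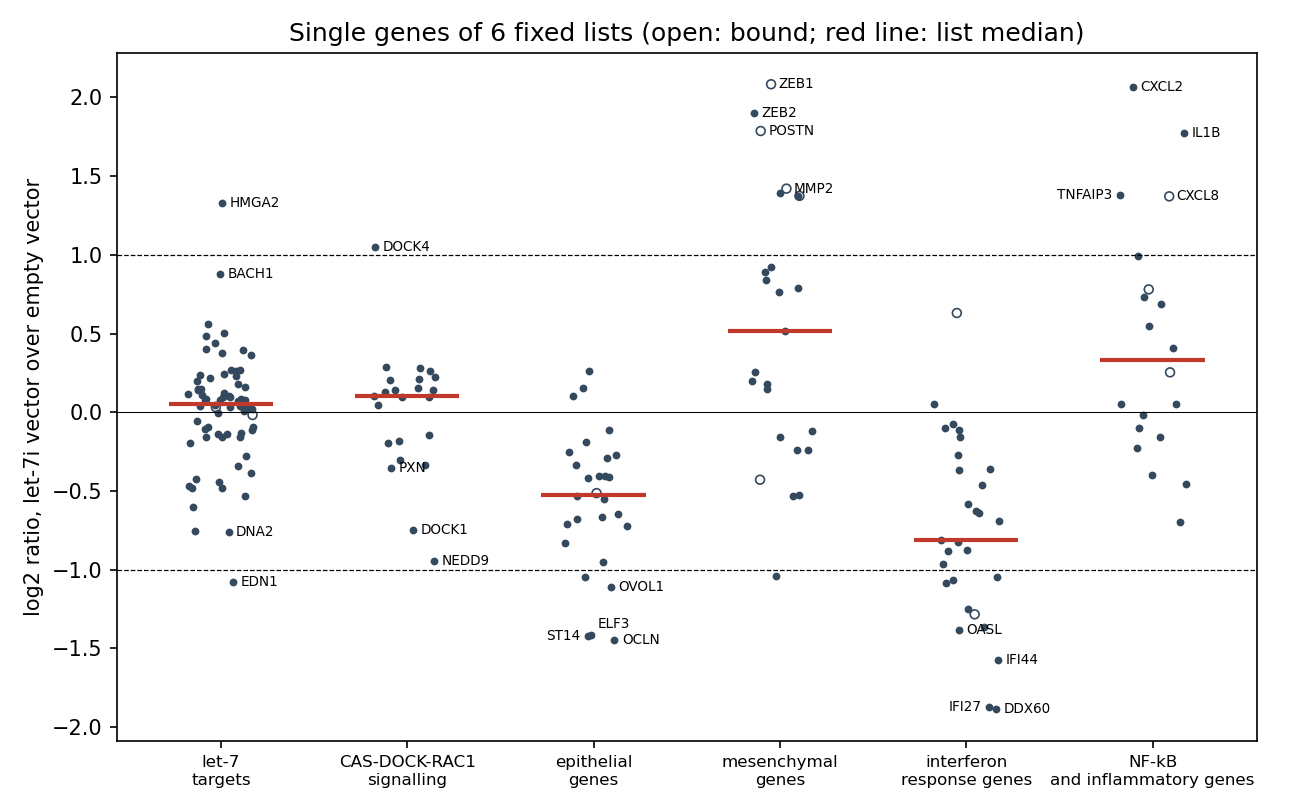
Log2 ratios (let-7i vector over empty vector, 1 array each) of the members of 6 fixed gene lists above the floor on at least 1 array. Each point is a gene, open points are lower bounds, red lines are list medians, dashed lines mark 2-fold, and the 4 members with the largest absolute ratio are named. Epithelial and interferon response genes lie mostly below 0, with medians of -0.52 and -0.81, and let-7 targets centre on 0.06.

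Interferon response genes were lower with let-7i more than any other list. Of 29 members above the floor, 27 were lower and 2 higher, and 10 were at least 2-fold lower. DDX60 had signals of 4925 and 1336 and IFI27 of 552 and 151. IFI44, an interferon-induced protein, was 2.97-fold lower, with log2 ratios of -2.09 and -1.57 in 2 probe sets, and OASL, an antiviral protein related to oligoadenylate synthetases, was 2.61-fold lower in its brightest probe set, with log2 ratios of -1.47 and -1.38. The median log2 ratio was -0.81, a 1.75-fold lower level, and 0 of 10000 random lists had a median as low.

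Several inflammatory and growth signalling genes were higher. CXCL2 was 4.18-fold higher, IL1B, an inflammatory cytokine, 3.42-fold, TNFAIP3, a feedback inhibitor of NF-kB, 2.60-fold and the chemokine CXCL8 at least 2.59-fold. Of 20 members of the NF-kB and inflammatory list 13 were higher, 4 of them at least 2-fold, and the median was 0.33 against a random range of -0.20 to 0.13. The median of the members measured on both arrays, a setting chosen after the data were seen, was 0.05 and lay within its random range, as did the median of 0.02 with a floor at the 65th percentile. That floor also took the calls of CXCL2 and CXCL8 away and cut the log2 ratio of IL1B to 1.14. Among immediate early and MAPK feedback genes, 21 of 23 members were higher and 2 lower, with a median of 0.34 against a random range of -0.14 to 0.14. DUSP6, a phosphatase that restrains ERK, was 2.38-fold higher in its brightest probe set and higher in both, FOSL1, an AP-1 subunit, was 1.86-fold higher, and HBEGF, a growth factor, at least 2.12-fold higher, a call lost with the mean of its probe sets (0.58). ETV5, an ETS transcription factor, was 1.81-fold higher, with 4 probe sets between 0.31 and 1.26.

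Cell cycle genes showed a small shift without large members. All 40 were measured, 25 were lower and 15 higher, and none was past 2-fold. The largest differences were in CCNE1 (1.49-fold lower), the replication factor CDC45 (1.37-fold), CCNE2 (1.35-fold) and E2F2 (1.26-fold), CCNE1 and CCNE2 being the E-type cyclins. The median of -0.05 lay below the random range of -0.03 to 0.10. Of 13 stemness genes 9 were lower, with a median of -0.26 against a random range of -0.18 to 0.16. ABCG2, a drug efflux pump, was 2.27-fold lower, ALDH1A3, an aldehyde dehydrogenase, had a log2 ratio of -0.59, SOX2 was 1.33-fold lower and SALL4 1.61-fold higher. This shift was -0.085, within the random range, with a floor at the 65th percentile.

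Ribosomal protein genes had a median of 0.04 and oxidative phosphorylation genes of 0.04, both within their random ranges, with no member past 2-fold. Polycomb genes, which encode chromatin repressors, had a median of 0.02 and microRNA biogenesis genes of -0.03, also within their ranges. The microRNA biogenesis median was -0.175 with the mean of the probe sets and -0.218 without probe sets shared between transcripts, both below the matching random range. EZH2, a Polycomb methyltransferase, was 1.20-fold lower, PHC2 was 1.38-fold higher in the brighter of 2 probe sets that disagreed (-0.19 and 0.47), and TUT7, a terminal uridylyltransferase, was 1.32-fold lower. Across the 24 lists with at least 3 members above the floor, 12 had medians outside the middle 95% of random lists, 5 lower and 7 higher, where chance gives 1.2 for lists of unrelated genes. Genes of 1 pathway vary together, so these positions describe the 2 arrays and not the conditions.

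**Figure D3:**
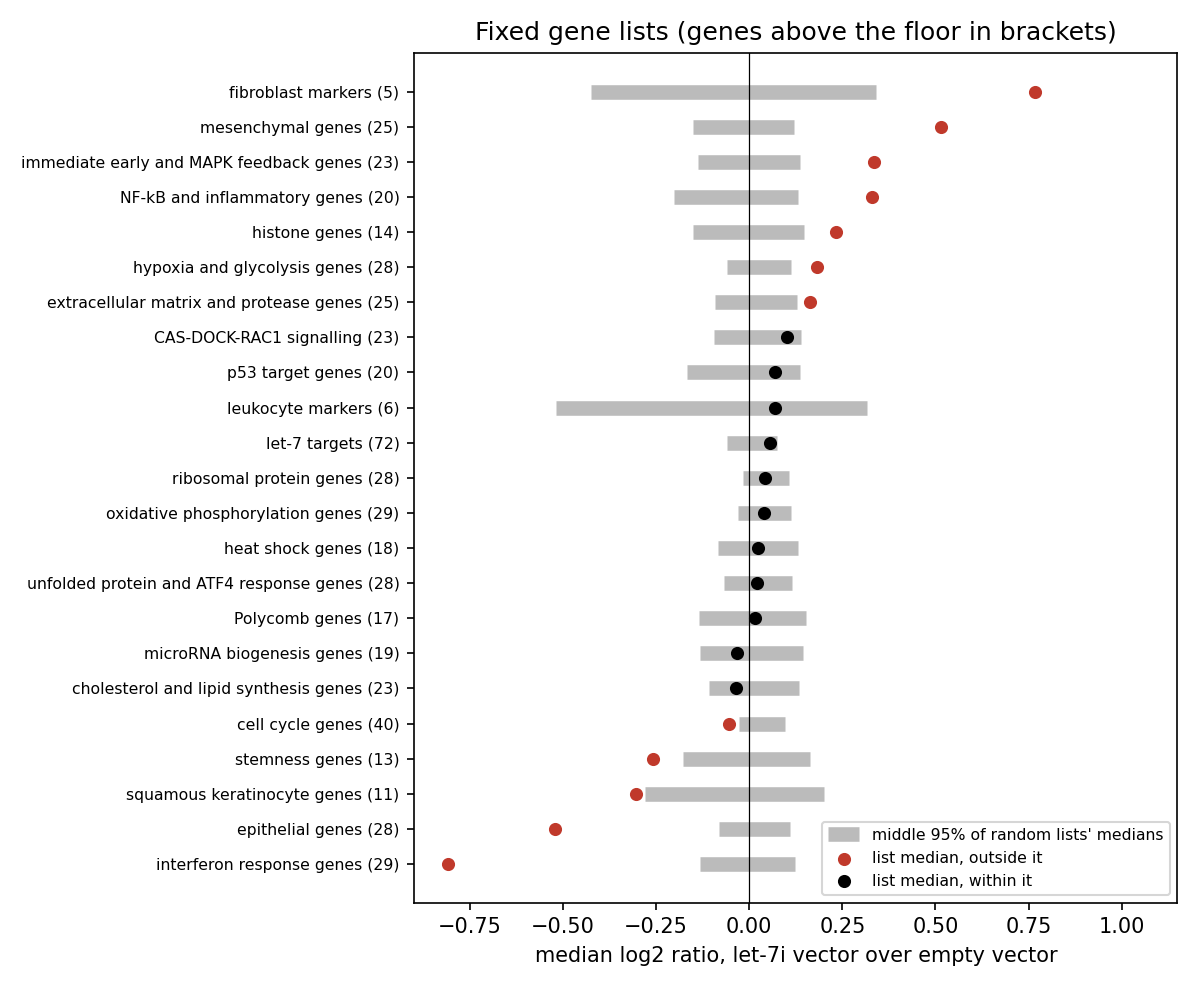
Median log2 ratio (let-7i vector over empty vector, 1 array each) of 23 fixed gene lists, with the number of genes above the floor in brackets. Grey bars span the middle 95% of the medians of 10000 random lists matched on signal, and red points are the 12 list medians outside it, from -0.81 for interferon response genes to 0.77 for fibroblast markers.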

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

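Both results here come from probe sets outside the comparison of named genes. Of 4130 probe sets that carry no single gene name and lie at or above the floor on both arrays, 76 were past 2-fold, 17 higher and 59 lower with let-7i. These probe sets were centred by the same constant as the named genes, and lowess centring was not tried on them. For named genes the direction with more calls depended on the scaling, with 154 higher and 145 lower after lowess centring. The first set of hybridization spike-in probe sets, which detect bacterial RNA added in fixed amounts, had a median log2 ratio of 0.55 (let-7i over empty vector), with 8 of 9 higher on the let-7i array, while the second set had a median of 0.11 with 9 of 9 higher.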

How the results depend on the processing

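No paired analysis was possible because each group had 1 array, and for the same reason no array could be left out. The test of seed matches in 3' UTRs was not run. The 130 higher and 169 lower genes became 654 and 1113 with a floor at the 25th percentile, 62 and 71 with a floor at the 65th, 514 and 728 at 1.5-fold, and 34 and 24 at 3-fold. The other settings stayed within 1.5 times the main counts, but after lowess centring (154 and 145) and quantile normalization (158 and 142) more genes were higher than lower, as at 3-fold. Without centring all 130 and 169 genes were kept, and after quantile normalization 129 and 140, against 94 and 127 with the mean of the probe sets, 94 and 118 without shared probe sets, and 62 and 69 with the floor at the 65th percentile. Of the 12 lists apart from random lists, 6 stayed apart in all 8 alternatives tried for lists: epithelial (medians from -0.541 to -0.495), mesenchymal (0.227 to 0.558), interferon response (-0.861 to -0.712), cell cycle (-0.089 to -0.038), hypoxia and glycolysis (0.138 to 0.255), and immediate early and MAPK feedback genes (0.265 to 0.359). Leaving out the centring moves a list and its random lists alike, so that alternative could not change a position. The other lists of the 12 came to lie within the random range in some settings, and the cause was not tested. Squamous genes did so after lowess (-0.219) and quantile normalization (-0.201), with the floor at the 25th percentile (-0.258) and with the mean of the probe sets (-0.15). NF-kB genes did so with the floor at the 65th percentile (0.017) and over genes measured on both arrays (0.052, added after seeing the data). Matrix genes did so with the floor at the 25th percentile (0.032) and the mean of the probe sets (0.113), stemness genes with the floor at the 65th (-0.085), histone genes without shared probe sets (0.078) and fibroblast markers with the floor at the 25th (0.203). Some lists moved outside the random range: let-7 targets upward with the floor at the 25th percentile (0.093), the CAS, DOCK and RAC1 list upward after quantile normalization (0.131) and with that floor (0.145), microRNA biogenesis genes downward with the mean of the probe sets (-0.175) and without shared probe sets (-0.218), and cholesterol genes downward without shared probe sets (-0.188). Of the named genes, CXCL8 turned from a bound of 1.37 to -0.015 with the floor at the 65th percentile, since its higher signal (228) is close to that floor (229 on the empty vector array). HMGA2 had a log2 ratio of 0.75 with the mean of its probe sets, which takes in bounds of dim ones, and IGF2BP3 of -0.86 without shared probe sets, where 1 dim probe set is left. Signal over background limits the dim genes, where most of the calls that depend on the floor lie.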

Other observations

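Of 28 hypoxia and glycolysis genes 22 were higher with let-7i, with a median of 0.18 against a random range of -0.06 to 0.11. NDRG1, a gene induced by hypoxia, was 2.29-fold higher, BNIP3, a mitophagy receptor, 1.95-fold, VEGFA, an angiogenic growth factor, 1.63-fold and EGLN3, an oxygen sensor, 1.54-fold (log2 ratio of 0.14 with a floor at the 65th percentile). Of 14 histone genes 11 were higher, with a median of 0.23 against a random range of -0.15 to 0.15. The linker histones H1-10 and H1-2 were 1.48-fold and 1.45-fold higher and H4C8 was 2.37-fold higher at a dim signal of 109 with the empty vector (log2 ratio of 0.16 with a floor at the 65th percentile). The histone median was 0.08, within its random range, without probe sets shared between transcripts. Of 20 p53 target genes 12 were higher, and their median of 0.07 lay within the random range. GADD45A, a stress-induced growth arrest gene, was 2.39-fold higher and the cell cycle inhibitor CDKN1A 1.65-fold higher. Cholesterol and lipid synthesis genes had a median of -0.04, within the random range, but of -0.188 and below it without probe sets shared between transcripts. SREBF2, the main activator of cholesterol synthesis genes, was 2.01-fold lower in its brightest probe set, while its 3 probe sets ranged from -1.01 to -0.10 and averaging probe sets and centring anew gave -0.41. Its brightest lay at the 2-fold threshold, between -0.99 and -1.02 in the other settings. Unfolded protein and ATF4 response genes and heat shock genes had a median of 0.02 each, within their random ranges. PPP1R15A, a phosphatase subunit induced by stress, had a log2 ratio of 0.997, just under the 2-fold threshold, and ATF3, a stress-induced transcription factor, was 1.63-fold lower.

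The tests in this part were chosen after the single gene ratios had been seen, and each explanation below is a hypothesis. Interferon response genes were lower on the let-7i array. A scaling or brightness trend between the arrays is argued against by the list's median, -0.81 before and -0.757 after lowess centring. Over 5 groups of measured genes ordered by signal, the median log2 ratio ran only from -0.09 to 0.03. The list's position among random lists cannot test such a trend, since those lists are matched on signal. A difference in RNA integrity is argued against by the 3'/5' ratios of GAPDH and ACTB, which differed between the arrays by at most 0.057 on the log2 scale, less than the SD of 1 probe set. Among what stays open is an effect of let-7i, which was not tested, and a difference in labelling or hybridization, not tested beyond these ratios. Hybridization spike-ins were higher on the let-7i array, with median log2 ratios of 0.55 in the first set and 0.11 in the second. Whether that difference bears on the list was not tested. Also open is a difference between transfected cultures that let-7i did not make, such as a higher interferon state of the empty vector culture. With 1 array per group these cannot be told apart.

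Epithelial genes were lower and mesenchymal genes higher on the let-7i array. After lowess centring the medians were -0.504 and 0.546, close to those before it (-0.52 and 0.52), which argues against a brightness trend. Their position among random lists cannot test such a trend, since those lists are matched on signal. A large share of fibroblasts in the let-7i culture is argued against because 9 of 14 fibroblast markers stayed below the floor there. Among them were the fibrillar collagen genes COL1A2 (signal 11.1) and COL3A1 (35.3), which fibroblasts express abundantly. Of the other 5 markers COL1A1 (346 and 415), DCN, FAP and POSTN were higher with let-7i and FBLN1 lower. Their median was 0.77, above the random range. A small share of fibroblasts cannot be excluded, since it could leave most markers below the floor. A drift of either culture that let-7i did not make may give the same shift and cannot be told apart from an effect of let-7i with 1 array per group.

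The let-7 target list was not lower on the let-7i array, and HMGA2 was higher. Dim members that hide a decrease are argued against by the 44 members brighter than the median gene, whose median was 0.046 against a lower random limit of -0.046. Whether members that moved with other lists hide a decrease stays open, since leaving out the 5 of 72 that stand in another list (median 0.046 of the other 67) could not have brought the median below random lists. Whether the let-7i line gained much mature let-7i cannot be told, since this kind of array does not measure the mature microRNA. Moreover, 0 probe sets were named for the let-7i gene or its host transcript, and such a probe set need not detect RNA made from the vector. LINC01465, the neighbour of let-7i in the RefSeq table, was below the floor on both arrays (75.0 and 76.0) and does not bear on this. A repression that acts on translation more than on RNA level, or an exchange of the labels of the 2 arrays, may also leave such a pattern, and neither was tested.

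A further hypothesis was that 1 of the 2 lines may have gained or lost chromosome segments. Over 546 windows of 20 neighbouring genes the medians had an SD of 0.0761, and 1 of 1000 shuffles of the gene order gave an SD as large (mean 0.0697, highest 0.0762). The window medians ran from -0.23 to 0.21. Neighbouring genes that are regulated together would raise this SD too, so the test leaves the hypothesis open.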
